A study of Homo sapiens with 8 samples.

How the data were processed

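CUT&RUN was used to map where a Flag-tagged form of the transcription factor SIX2 sits in the genome of adult human pancreatic islet cells. In this assay an antibody tethers a protein A-micrococcal nuclease fusion to the chromatin-bound target, and the short DNA fragments that the nuclease releases are sequenced. Per the labels' protocols, dispersed primary islet cells were transduced with lentivirus that expressed SIX2-Flag, cultured for 5 days, and sequenced as paired-end libraries. The labels divide the 8 libraries into 4 made with an anti-Flag antibody and 4 made with control IgG.

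Per the submitters' processing notes, Trimmomatic, Bowtie2, HOMER and the hg19/GRCh37 genome were used, with no versions given. Per the file headers, each deposited list was made by HOMER mergePeaks with a joining distance of 100 bp from peak files of single anti-Flag libraries. Replicates were therefore called singly and then joined. The peak-calling settings, and whether the IgG libraries served as the background, are not given in the sources used here. The header of the earlier list names 2 input peak files, whereas 3 anti-Flag libraries cite that list in their labels (replicates 1, 2 and 4). The header of the later list, which the labels mark as made after publication, names 3 input files (replicates 1, 2 and 3). The lists thus share libraries. The deposited score of each row is a whole number, and its meaning is given neither by the headers nor by the labels. Here it ranks rows within a list and is compared, on a log2 scale, between shared and unshared loci of a list. Scores of the same loci in the 2 lists are also set side by side. Loci in both lists were ranked by the higher of their 2 scores, although it is unknown whether the scores of the lists share a scale. The other deposited values are peak starts and ends.

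Rows on the 22 autosomes were used, and sex chromosomes were left out because the cells came from donors. This is narrower than the design fixed before the data were examined, which had kept chromosome X. Every row name in the deposited lists carries the number of input peaks that were joined, which was 2 in the earlier list and 2 or 3 in the later one. In the earlier list some rows overlapped one another, which a single merge would have joined, so rows that shared at least 1 base were combined into loci. A locus with 2 or 3 overlapping rows was taken to hold peaks of 3 libraries, an assumption from the labels that the rows themselves do not show. Per the file headers, the peak files joined in the 2 lists have different names, also where they come from the same library. Coordinates are given 1-based on hg19. Read depth is unknown from these lists, no value belongs to a single library, and no replicate error can be computed. Exact Clopper-Pearson and Poisson intervals (95%) cover counting error only. Neighbouring loci are not independent, so these intervals are too narrow where loci cluster. No columns of per-sample values were present (0).

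Loci were called shared when they had at least 1 base in common. The number shared was set against 1000 random placements of the later list on the same chromosomes (a two-sided permutation of positions, smallest possible p = 0.002). Assembly gaps could not be excluded from the placements, since no hg19 sequence was used here. Shares of loci were compared by two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment over the 22 autosomes. For these, loci found in one list only were used. Densities are loci per Mb of 1 Mb windows that held a locus of either list (2696 windows). Log2 scores of shared and unshared loci were compared by a permutation test with 100000 resamples. The distance between the 2 input peaks of a row was taken as the row width minus 101 bp, the smallest width in either list. Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3.

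The methods were tested on simulated data. With 500 loci made common to a randomly placed list of 11484 loci, the excess over chance was 504 loci. With 20% of 16294 distances made short, 19.5% was recovered, and with 20% of 11215, 16.7%. All 4 of 4 chromosomes raised by simulation among 22 were found. They were raised by more than the largest odds ratio reported below, the simulated loci did not cluster, and false calls were not counted. In 3 simulated libraries of 300000 peaks each, the formula for 3-library loci under independent placement gave 224 and the simulation 236.

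Tests of SIX2 motifs, of promoters and introns, and of 21 gene lists had been fixed before the data were examined. They need hg19 sequence or gene positions, which were not used here. The rule for naming genes provided for this case: no gene is named from a position, and the 10 highest-scoring loci in both lists (12 with ties) are given by coordinates. Loci counted as 3-library loci in both lists are also given, chosen after their values were seen.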

Results

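SIX2, a homeodomain transcription factor known from adult human beta cells, was expressed with a Flag tag in adult primary islet cells, and its genomic positions were sought by CUT&RUN. The series comprises 4 anti-Flag and 4 IgG libraries. Processed values were available as 2 pooled lists of anti-Flag peaks in hg19 coordinates, so the IgG signal was not analysed here and read depth is unknown. The earlier list draws on anti-Flag replicates 1, 2 and 4 by its labels, and the later list on replicates 1, 2 and 3 by its header. The design implies 3 questions that these lists can address: how many regions were marked in at least 2 libraries, where they lie, and how far the 2 lists name the same regions.

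Anti-Flag peaks found in at least 2 libraries were numerous and spread over every autosome. The earlier list held 15704 autosomal loci in 16294 rows and the later list 11484 loci. Together the earlier loci covered 2.36 Mb and the later loci 1.69 Mb. Rows had a median width of 149 bp in the earlier list (interquartile range 124 to 174 bp) and 145 bp in the later list (122 to 171 bp). These widths follow from joining peaks of fixed width within 100 bp and do not measure the bound regions. Loci taken to hold peaks of 3 libraries were a small minority in both lists. They numbered 372 in the earlier list (2.37% of loci, 95% exact interval 2.14 to 2.62%) and 269 in the later list (2.34%, 2.07 to 2.64%).

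Peak loci were densest on chromosomes 17, 19 and 22 and sparsest on chromosome 4 in both lists. In the earlier list the density ran from 5.05 loci per Mb on chromosome 4 (95% Poisson interval 4.73 to 5.38) to 7.14 on chromosome 22 (6.28 to 8.09), a 1.42-fold range. The later list had a wider range of 2.06-fold, from 3.04 loci per Mb on chromosome 4 (2.79 to 3.30) to 6.27 on chromosome 17 (5.73 to 6.84). Chromosome 19 held 6.95 loci per Mb in the earlier list and 5.95 in the later list. Chromosomes 18 and 21 held 3.55 and 3.05 loci per Mb in the later list, against 5.86 and 5.42 in the earlier list.

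**Figure D1:**
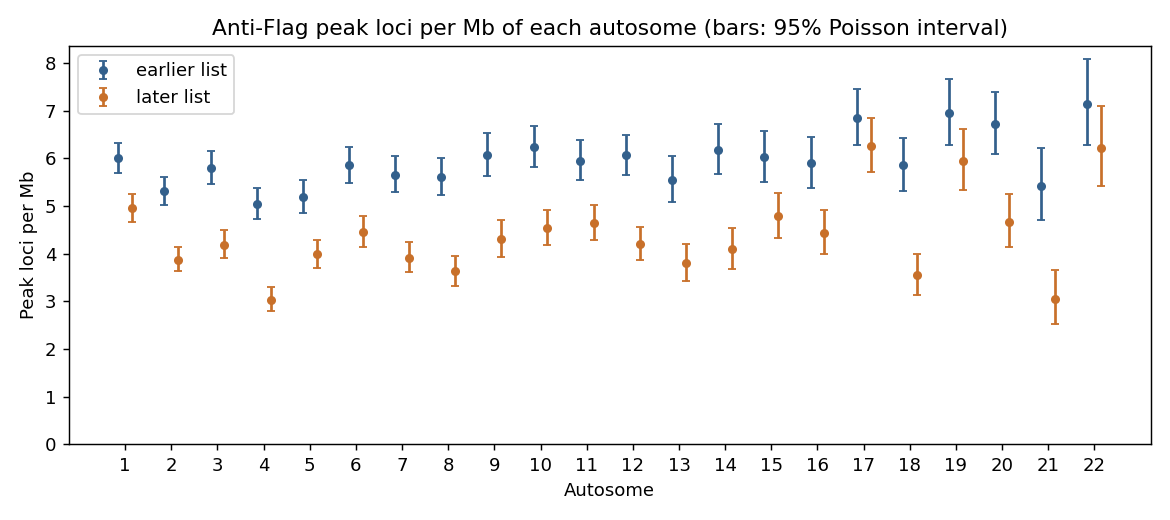
Peak loci per Mb (vertical axis) on each of the 22 autosomes (horizontal axis) in the earlier and the later list, with 95% Poisson intervals as bars. The later list ranges from 3.04 on chromosome 4 to 6.27 on chromosome 17, a wider spread than the earlier list.

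Loci found in one list only were then compared by chromosome (12819 earlier, 8599 later). By Fisher's exact test with Benjamini-Hochberg adjustment over 22 autosomes, chromosomes 1 and 17 held a larger share of later-only than of earlier-only loci. Chromosomes 4 and 18 held a smaller one. This sets 1 pooled list against 1 other, so the p-values of this paragraph measure no spread between replicates. Such loci can also rest on a peak of a shared library. Chromosome 17 held 4.29% of later-only against 3.24% of earlier-only loci (odds ratio 1.34, Fisher's exact test, adjusted p = 0.00077). Chromosome 1 held 9.97% against 8.57% (odds ratio 1.18, Fisher's exact test, adjusted p = 0.0043). Chromosome 4 held 4.92% against 6.25% (odds ratio 0.78, adjusted p = 0.00077), and chromosome 18 held 2.22% against 2.86% (odds ratio 0.77, adjusted p = 0.024), again by Fisher's exact test. Loci cluster, so a permutation test on 5 Mb windows was added after seeing the data; in it chromosomes 1, 4 and 17 passed (adjusted p = 0.049, 0.0029 and 0.030) and chromosome 18 did not (adjusted p = 0.071). Among the higher-scoring, then wider, 50% of loci of each list, 0 of 22 chromosomes differed, so that none of the 4 calls was made there. Most scores were 1, so width mainly set this choice, and wider 2-library rows join peaks that lie farther apart. The subset also holds fewer loci, so it is a less sensitive test and no check on better-supported loci.

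At the scale of 1 Mb, loci were more clustered than random scatter in both lists, and more so in the later list. Across 2696 windows of 1 Mb, the variance of the locus count divided by its mean, which is 1 for random scatter, was 1.27 in the earlier list (95% bootstrap interval 1.21 to 1.34) and 1.98 in the later list (1.88 to 2.09). In windows of 0.5 Mb the earlier list gave 1.03 (0.99 to 1.07) and the later list 1.48 (1.42 to 1.54). Only windows that held a locus of either list were counted, 5230 at this size. Leaving out empty windows lowers the ratio, so an interval that includes 1 does not show random scatter there. In windows of 5 Mb the earlier list gave 2.82 (2.44 to 3.22) against 4.19 (3.73 to 4.65) in the later list. The highest counts in a 1 Mb window of either list alone were 16 earlier and 17 later loci. Ranked by the smaller of its 2 counts, the first window was chromosome 9, 130000001 to 131000000, with 14 earlier and 16 later loci. It was followed by chromosome 1, 177000001 to 178000000, with 15 and 13 loci, by chromosome 12, 1000001 to 2000000, with 13 and 13, and by chromosome 13, 27000001 to 28000000, with 12 and 15. With shared loci left out, counts per window in the lists were weakly correlated (Pearson r = 0.18, Spearman rho = 0.18, permutation p = 1e-05 for each, the smallest 100000 permutations can give, and for both after Benjamini-Hochberg adjustment over 2 coefficients). Without the 2 windows farthest from the median, r was again 0.18. Windows are not independent replicates, and a locus in one list only can rest on a peak of a shared library. The correlation therefore does not measure agreement of independent data.

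Within a row, the peaks of 2 libraries lay at all distances up to the 100 bp limit, with a modest excess of short distances that was larger in the later list. The median distance was 48 bp in the earlier list and 43 bp in the later list. Peaks lay within 50 bp of each other in 52.7% of 16294 earlier rows (51.9 to 53.5%) and in 57.2% of 11215 later rows from 2 libraries (56.3 to 58.1%), where an even spread would give 50.2%. The difference between the lists was 4.50 percentage points (Fisher's exact p = 1.89e-13), with rows counted as independent. Peaks centred on the same base occurred in 72 earlier and 52 later rows, no more than an even spread would give. The excess thus lay at other short distances.

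**Figure D2:**
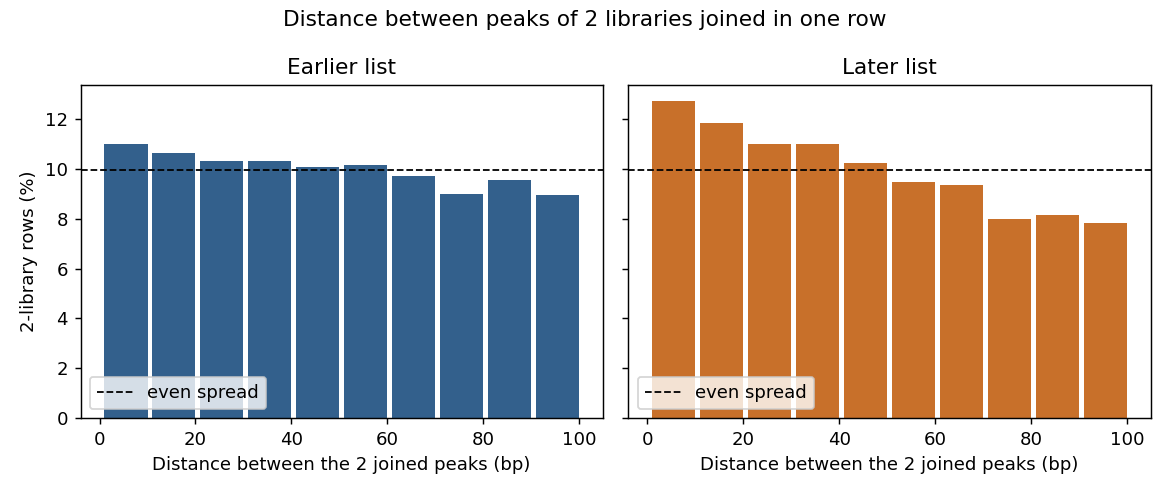
Percentage of rows joined from 2 libraries (vertical axis) by the distance in bp between their 2 peaks (horizontal axis, bins of 10 bp, rows at distance 0 left out) in each list, with the even-spread level of 9.95% as a dashed line. The earlier list falls from 11.004% at 1 to 10 bp to 8.94% at 91 to 100 bp, and the later list from 12.7% to 7.81%.

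The lists named the same regions far more often than random placement did, as lists that share libraries would. A total of 2885 loci were common, which is 18.4% of the earlier list (17.77 to 18.99%) and 25.1% of the later list (24.3 to 25.9%). Random placement gave 19.6 on average and at most 34 in 1000 placements (two-sided permutation of positions, p = 0.002, the smallest these can give). Pairs of peaks from libraries used in both lists enter both by construction, so this test is no independent evidence of agreement. Of the common loci, 1995 had identical coordinates in both lists, as a pair of peaks from libraries used in both would give. Without those, 890 later loci (9.38%) overlapped an earlier locus against 16.0 by random placement, and these too can rest on a peak of a shared library.

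Loci counted as 3-library loci recurred in the other list more often than 2-library loci, as the way the lists were joined would itself give. In the later list, 248 of 269 such loci (92.2%, 88.3 to 95.1%) were also in the earlier list, against 2637 of 11215 loci from 2 libraries (23.5%). In the earlier list the counts were 181 of 372 (48.7%, 43.5 to 53.9%) and 2704 of 15332 (17.6%). A 3-library locus of the later list contains peaks of replicates 1 and 2, which both enter the earlier list. An earlier locus of 2 or 3 rows is wider than one of a single row and, on the reading used here, more often holds a pair of replicates 1 and 2. The difference in recurrence is therefore no independent evidence in either list, and no p-value is given for it. Of 218 earlier loci with 3 overlapping rows, 116 recurred (53.2%, 46.35 to 59.98%). All 218 would recur if the 3 rows were the pairs of replicates 1, 2 and 4 and the same peak calls entered both lists, so at least one of these did not hold throughout.

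**Figure D3:**
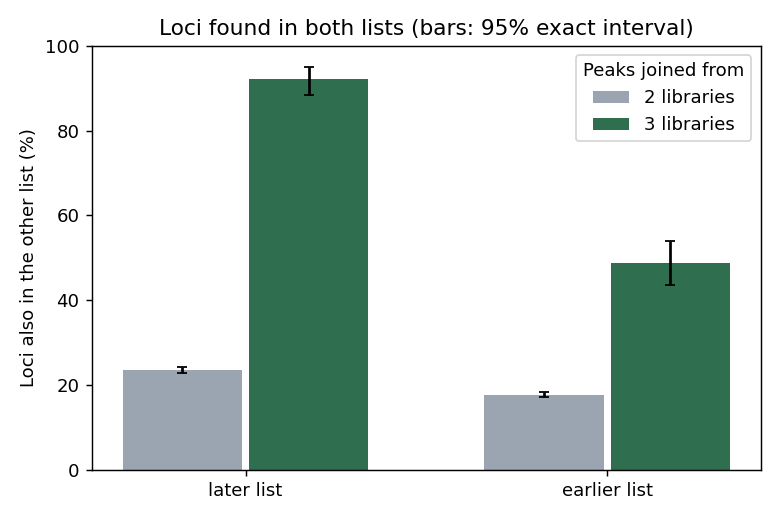
Percentage of loci also found in the other list (vertical axis) for loci counted as 2-library or 3-library loci in each list, with 95% exact intervals as bars. In the later list the count is that of joined input peaks. In the earlier list loci of 2 or 3 overlapping rows are taken as 3-library loci, which the rows themselves do not show. In the later list 92.2% of 3-library loci recur, against 23.5% of 2-library loci.

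Only 22 loci, 0.19% of the later list, counted as 3-library loci in both lists, on the reading of overlapping earlier rows that the 116 of 218 above leaves uncertain. They lay on 11 autosomes. Chromosome 3 held 4 of them, at 15244391 to 15244575, 93699026 to 93699170, 100120110 to 100120223 and 169658605 to 169658774. Chromosome 7 held 3, at 23497899 to 23498024, 86689193 to 86689341 and 148788477 to 148788639. Chromosome 17 also held 3, at 2751447 to 2751657, 4607211 to 4607454 and 7591573 to 7591778. Pairs lay on chromosome 2 (109855282 to 109855463 and 218090280 to 218090422), chromosome 8 (61967028 to 61967240 and 62051825 to 62051995), chromosome 11 (10772512 to 10772646 and 13204968 to 13205165) and chromosome 22 (35695885 to 35696087 and 38660434 to 38660633). Single loci lay on chromosome 1 (77993824 to 77994065), chromosome 5 (154147127 to 154147310), chromosome 6 (158772195 to 158772430) and chromosome 16 (56659377 to 56659606). Each of the 22 had a score of 1 in the later list.

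The authors' score separated few loci. It was 1 for all but 142 of 16294 earlier rows (0.87%) and all but 45 of 11484 later rows (0.39%). The highest-scoring region of either list was chromosome 2, 45235862 to 45236045, a 3-library locus with a score of 55352 in the later list, followed by chromosome 5, 134260222 to 134260324, with 352. Neither region was checked for reads from near-identical sequence elsewhere, since no hg19 sequence was used. Such sequence could be the lentiviral SIX2 sequence or copies of mitochondrial DNA in the nuclear genome. The chromosome 2 locus was also in the earlier list, from 2 libraries, with a score of 1. The highest score in the earlier list was 23, at chromosome 15, 20554938 to 20555124. Loci in both lists were ranked by the higher of their 2 scores, and the chromosome 2 locus came first. The next highest were at chromosome 1 (110185972 to 110186090), chromosome 17 (3539804 to 3539906), chromosome 19 (46736977 to 46737104) and chromosome 2 (53994780 to 53994891). All 4 scored 15 in the earlier list and 1 in the later list; positions are those of the later list. Loci at chromosome 15 (85144134 to 85144319) and chromosome 3 (126373722 to 126373907) scored 14 in both lists, chromosome 1 (230220608 to 230220712) scored 13 in both, and chromosome 13 (44619377 to 44619543) scored 14 in the earlier list and 1 in the later. The remaining 3 of the 12, on chromosome 17 (4607211 to 4607454 and 33569111 to 33569289) and chromosome 8 (19675084 to 19675189), scored 13 in the earlier list and 1 in the later list.

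Score did not differ detectably between loci in both lists and loci in one. In the earlier list the mean log2 score was 0.023 for shared and 0.027 for unshared loci (permutation p = 0.51, two-sided, adjusted 0.89 over 2 lists). In the later list it was 0.014 and 0.013 (permutation p = 0.89, adjusted 0.89). Without the locus scored 55352 the later means were 0.0085 and 0.013, the opposite direction, again short of the threshold (permutation p = 0.29). Scores above 1 were found in 0.62% of shared (0.37 to 0.98%) and 0.97% of unshared loci (0.81 to 1.15%) of the earlier list. In the later list these shares were 0.28% (0.12 to 0.55%) and 0.43% (0.30 to 0.59%).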

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

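Rows on contigs outside the assembled chromosomes, which no comparison used, were above the limit of 3 that a count of 0 allows. Nothing in the design makes 0 the count to be met there, so passing this limit is no sign of an excess. The earlier list held 16 such rows and the later list 5, all with a score of 1. No IgG list was analysed here to set beside them.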

How the results depend on the processing

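Of 27 alternatives tried over 12 results, 19 left the direction and the side of the threshold (or the count within 1.5 times) as reported, 7 moved a value, among them the number of chromosome calls, which went from 4 to 0 in one of them, 1 other result fell short of its threshold and none (0) reversed a called direction. The shared part of the later list stayed between 9.38% (without identical loci) and 25.1%, above random placement under each alternative. The shared libraries would themselves give this, so it is no evidence of independent agreement. With the lower-scoring, then narrower, 50% of loci removed from each list, the lists held 7852 and 5742 loci, fewer by construction. Width mainly set this choice, since most scores were 1. There 0 chromosomes differed in share, so none of the 4 chromosome calls was made. Loci counted as 3-library loci made up 4.01% and 3.67% of these lists, since such loci are wider. All loci of both lists, or 5 Mb windows permuted, gave 3 chromosomes (1, 4 and 17), without chromosome 18. In windows of 0.5 Mb the scatter of the earlier list was 1.03, with an interval that includes 1. Empty windows were left out, which lowers this value, so it does not show random scatter at that size. The score difference between shared and unshared loci of the later list, 0.00081 on the log2 scale, was -0.0046 without the highest-scoring locus, and the odds ratio of a score above 1 was 0.64. Neither passed the threshold, and the cause was not tested. The chromosome comparison, window scatter and peak distances, with all their settings, were added after seeing the data, as were the score alternatives, rows as deposited, and the overlap without identical loci or with only 2-library peaks. The list counts and the overlap with its other settings had been planned. The score comparison had too, but not its log2 scale. Alternatives for motifs, annotation and gene lists, for the SIX2 gene and for assembly gaps were not run, because hg19 sequence and gene positions were not used here. Leaving out single replicates was not possible, since rows carry no library. No paired analysis was possible because the lists pool libraries and hold no IgG values.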

Other observations

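All tests in this part were chosen after the result they bear on had been seen, and the text gives their outcome as hypotheses only.

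Peaks of 2 libraries joined in one row lay at all distances up to 100 bp, with fewer rows at long than at short distances: from 1 to 10 bp to 91 to 100 bp the share fell from 11.004% to 8.94% in the earlier list and from 12.7% to 7.81% in the later list. Against the even spread of 50.2% within 50 bp, the exact binomial p was 3.3e-10 in the earlier list and 2.5e-49 in the later list, with rows taken as independent. If distances of 81 to 100 bp give the flat level, 7.2% of earlier rows (4.1 to 10.2%) and 19.8% of later rows (16.4 to 23.2%) stood above it. Independent chance positions in each library are argued against as the whole cause in both lists. The shares of 52.7% and 57.2% exceed an even spread. Loci taken as 3-library loci numbered 372 in the earlier list. A formula for independent placement with equal pairings gave 164, a ratio of 2.27 (2.04 to 2.51). The 372 are overlapping rows, which need not share a peak as the formula requires, and the 116 of 218 above leaves their reading uncertain. In the earlier list the argument therefore rests on the share within 50 bp. In the later list 3-library loci numbered 269 against 104 by the formula, a ratio of 2.59 (2.29 to 2.92). The formula is no upper bound, since a simulation gave 236 where it gave 224, and the intervals cover counting error only. That chance accounts for a large part of the 2-library rows stays open, because the number of peaks per library was not analysed here. Broad bound regions, in which a peak of fixed width may fall anywhere, also stay open: loci 0.5 to 2 kb apart were 0.79 times as dense as at 20 to 100 kb in the earlier list (0.65 to 0.95) and 1.59 times as dense in the later list (1.35 to 1.86), and a peak caller can remove close neighbours.

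The score of 55352 on chromosome 2 was 157 times the next highest in the later list, and the same start position scored 1 in the earlier list. Of the 269 3-library loci in the later list, this one and chromosome 2, 45233414 to 45233523, formed the only pair (1) within 5000 bp of each other. Shared loci scored above 1, with the highest score of all joined rows taken for an earlier locus, had equal scores in 5 of 7 cases with identical coordinates and in 0 of 14 with other coordinates (Fisher's exact p = 0.00103). Compared row by row instead, 1994 of 1995 identical rows, most of them scored 1, had equal scores. Identical rows can be the same joined pair and then carry equal scores by construction. The test therefore cannot show what the score depends on. At the 14 loci with other coordinates the scores differed between the lists, and the cause was not tested. A dependence on which input peaks were joined stays open. It would bear on the difference between lists and not on the size of 55352. SIX2 itself lies on chromosome 2, so DNA of the lentiviral SIX2 sequence is a candidate source of this signal. It cannot be told apart from binding here, because the locus was not placed in a gene.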
